A study of Homo sapiens with 12 samples.

How the data were processed

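HD-MyZ cells were profiled in 12 samples, 3 in each of 4 groups: control, 10 µM perifosine, 5 µM sorafenib, and both drugs, all after 24 hours. Per the labels' protocols, RNA was extracted with Trizol and column-cleaned with DNase treatment, its quality was checked on a Bioanalyser, and biotinylated cRNA was made for Illumina arrays. BeadStudio is the tool named in the submitters' processing notes, with its version and its normalization setting not given in the sources used here. The deposited intensity values are on a linear scale with 1 value per probe and sample. From the values, the sorted columns of all 12 arrays differ by at most 2.35%, all values are above 0 and the lowest is 170, so they look quantile normalized with no background subtracted. A table of signals without normalization has 12 signal columns whose names match no sample's labels. Those 12 columns were not used here, since columns cannot be given to samples by order or value. The comparisons, the other settings to try, the rule for naming genes and the gene lists were fixed before the data were examined. The plan was background correction from the detection p values of that table, followed by a detection filter. In its place the plan's fallback was used: log2 of the deposited intensities, with no further normalization, background correction or filter. No background being subtracted, log2 changes of dim genes are understated.

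Probes were named through the platform annotation supplied with the series. Of 48803 probes, 28098 had exactly 1 gene symbol, 13 had several and 20692 were not listed there and are unnamed here. Symbols were compared through Entrez identifiers with the RefSeq gene table of assembly GRCh38.p14, which was used for names alone. It held 28059 of the listed probes' genes and lacked 52, and 0 symbols were changed by it. No coordinates are given, since no build is named for the array. For each of 18852 genes the probe with the highest mean log2 intensity was kept, and 6132 genes had more than 1 probe. For the genes taken by the rule below and others followed with them, some of which are not printed in the report, 113 of 135 other probes had the same sign of change and 22 the opposite sign, each comparison counted. All 22 had a mean log2 intensity of 8.81 or less, near the background, and belong to BDNF, CLN8, DCN, FBLN1, FBXO32, IRF7, MEST, NOP2, SLC6A9, SYTL2, TSC22D3 and UNG.

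The groups were compared with limma 3.58.1 in R 4.3.3. A model of 4 group means was fitted to all 12 arrays, which leaves 8 residual degrees of freedom and 3.52 prior degrees of freedom. Moderated two-sided tests were made for 6 contrasts: each treatment against control, the combination against each drug, and the interaction, which is the perifosine effect with sorafenib minus that without it. P-values were adjusted by Benjamini-Hochberg over the 18852 genes of a contrast, with a threshold of 0.05. Genes that passed were also counted at a change of at least 2-fold.

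In all, 27 gene lists with 558 entries were fixed, of which 517 entries had a probe. They covered the amino acid response (ATF4 targets), cytosolic aminoacyl-tRNA synthetases, ER chaperones, cholesterol synthesis and uptake, fatty acid synthesis, ERK pathway output, FOXO targets, mitosis, DNA replication, p53 targets, the BCL2 family, autophagy and lysosome, oxidative stress, heat shock, hypoxia and glycolysis, oxidative phosphorylation, ribosome biogenesis, NF-kB targets, the interferon response, metallothioneins and Hodgkin cell markers. Markers of T cells, B and plasma cells, monocytes and macrophages, epithelium, and fibroblasts and stroma stood for other cell types. The list of mitochondrially encoded transcripts had no named probe and could not be tested, so 26 lists were. Each was tested against all other genes with camera at its preset correlation of 0.01, adjusted over the 26 lists of a comparison. The test was repeated with a correlation estimated from the data, and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. The number of members past the threshold is given over all genes tested and adjusted over the list alone.

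Genes were named by a rule. For each comparison it took the 5 largest rises and the 5 largest falls among called genes without overlap, leaving out placeholder symbols. It also took up to 2 members of each list with at least 25% of its members called (1 member outside the comparisons with control), and TRIB3 in every comparison. All other genes in the text, the next 5 each way and further list members, were named after their values were seen.

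Arrays were compared with their group mates before the fit, by Pearson correlation of log2 intensity over all genes tested. An array was said to stand apart where the correlation of the 2 other arrays of its group with each other exceeded its own mean correlation with them by more than 0.005, a limit set after the data were seen. It applied to 3 arrays. Deviations of an array were taken from the mean of its group mates. The replicate letters are shared by the groups, but the labels do not say that they mark a common day.

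The fit was tested on simulated data of 18852 genes with the spread of these arrays, for the combination against control. Of genes changed by 1.5-fold, 38.7% were recovered, against 76.7% at 2-fold and 97.9% at 4-fold. False calls were 4.77% of calls, and on average 0 genes were called where nothing was changed. Of 10 lists shifted by 0.5 log2, 10 were called, and 0 of 250 unshifted lists were. The simulated genes were drawn independently of each other, so these list values do not cover lists whose genes are correlated. In the real arrays the estimated correlation within a list reached 0.54, for metallothioneins.

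The settings fixed then that could be run as alternatives were the mean of all probes of a gene, every probe as its own row, a fit of the 2 groups compared, the replicate letter as a block, eBayes with trend and robust, and leaving out each array in turn. Alternatives added after the data were seen were leaving out the 3 arrays that stood apart, array quality weights, normexp background correction of the deposited intensities with an offset of 16, and keeping the 9587 genes with a mean log2 intensity of at least 9 (an intensity of 512).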

Results

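Gene expression was measured in HD-MyZ, an established human cell line derived from a Hodgkin lymphoma. Cultures were exposed for 24 hours to 10 µM perifosine, to 5 µM sorafenib, to both drugs, or to neither. Perifosine is an alkylphospholipid that inhibits the kinase AKT. Sorafenib inhibits RAF and several receptor tyrosine kinases. Each of the 4 groups had 3 arrays (replicates A, B and C), which makes 12 arrays of biotin-labelled cRNA on an Illumina beadchip. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples. After 1 row was kept per gene, 18852 genes were tested. The deposited intensities ran from 170 to 71906 with a median of 322, and 70.2% of the probes lay under 512 on average, close to the densest intensity of 277. The number of arrays limits the precision of every value below.

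The arrays did not split by treatment alone. Over the 9587 genes with a mean log2 intensity of at least 9, the first principal component held 51.7% of the variance and set apart control C, sorafenib B and combination A from the other 9 arrays. The second held 19.7%, and among those 9 arrays it parted the arrays with sorafenib from those without. In the 3 arrays that stood apart, 28 nuclear-encoded genes of oxidative phosphorylation lay below their group mates by a median log2 of -0.36 in control C, -1.0 in sorafenib B and -0.40 in combination A. Metallothionein genes lay lower as well, at -1.78, -1.66 and -1.55. All 12 arrays were kept, and each count of changed genes is also given without these 3 arrays, a choice made after the data were seen.

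The comparison of perifosine with control asked what perifosine alone changed. The largest rises were in matrix metalloproteinases and chemokines. MMP10 (stromelysin-2) went from an intensity of 1275 ± 122 (SD, n = 3) to 9115 ± 1405, a log2 change of 2.83 (SE 0.21, adjusted p = 0.000226 by limma). MMP1, the interstitial collagenase, went from 356 ± 26.6 to 1774 ± 365, a log2 change of 2.30 (SE 0.14, adjusted p = 3.13e-05). Its control value lies close to the background, so this change is understated, and with normexp background correction it was 3.21. The chemokine genes CCL3 and CCL3L3 rose by log2 values of 2.15 and 2.17 and CCL3L1 by 1.69. These 3 genes are near-identical copies, so their probes may read one another's transcripts and the assignment between them is uncertain. RHOB, a small GTPase gene, rose by 2.00, NPPC (C-type natriuretic peptide) by 1.93, and STING1, the adaptor of cytosolic DNA sensing, by 1.47. The largest falls were in KRTAP4-7 (-1.29), MEST (-1.23), APLN, which encodes the peptide apelin (-1.18), CPA4 (-1.15) and OSR1 (-1.09). In all, 56 genes changed, 38 of them upward and 18 downward, and 18 rose and 7 fell by at least 2-fold. Without the 3 arrays that stood apart the count was 293, among them all 56. It was also sensitive to single arrays: 21, 13 and 27 genes without control A, B or C, 17, 11 and 14 without perifosine A, B or C, and 155 without sorafenib B, which enters only through the shared spread. Of 28 called genes followed through each single array left out, 7 passed every time (MMP10, MMP1, CCL3L3, CCL3L1, RHOB, FERMT1 and ARSB). The calls of CCL3, NPPC, STING1, KRTAP4-7, MEST, APLN, CPA4 and OSR1 each ended without at least 2 of the control or perifosine arrays.

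With perifosine alone, 13 of the 26 gene lists tested differed from other genes by camera, of which 6 also did so with an estimated correlation. Genes of DNA replication and the G1/S transition were lower, with a median log2 change of -0.44 over 30 measured genes (adjusted p = 1.46e-19 by camera, 0.0151 with an estimated correlation). CDT1, a replication licensing factor, fell by 0.74 and UNG, a uracil-DNA glycosylase, by 0.70, and these 2 alone passed over all genes, against 15 that fell when adjusted over the list alone. Both calls ended in 12 of 21 alternatives, among them each control or perifosine array left out, with an adjusted p of up to 0.254 for CDT1 and 0.588 for UNG. With the mean of its probes UNG was at -0.32. Genes of cholesterol synthesis and uptake were higher as a list, with a median of 0.33 over 20 genes (adjusted p = 9.62e-07, 0.0442 with an estimated correlation), but 0 of them passed singly, also when adjusted over the list alone. Among them were IDI1 (0.64, adjusted p = 0.266) and HMGCS1 (0.63, adjusted p = 0.555). Ribosome biogenesis genes were lower (median -0.22 over 28 genes, adjusted p = 0.00016), and genes of the interferon response (0.16 over 25, adjusted p = 9.91e-05), autophagy and the lysosome (0.13 over 27, adjusted p = 0.00106) and Hodgkin cell markers (0.12 over 16, adjusted p = 0.00405) were higher. Each of these 4 lists had an adjusted p of 0.0442 with an estimated correlation and 0 members past the threshold over all genes. When adjusted over the list alone, 3 interferon genes and 2 Hodgkin cell markers rose, the latter being TRAF1 (0.85, adjusted p = 0.209 over all genes) and JUNB (0.73, adjusted p = 0.281).

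The remaining 7 lists called with perifosine lost the call with an estimated correlation. In the 9 arrays left without those that stood apart 14 lists were called by camera, the 13 and the synthetase genes (median 0.09, adjusted p = 0.0443, against -0.02 and adjusted p = 0.877 in all 12). Output genes of the ERK pathway were higher (median 0.21 over 24 genes, adjusted p = 3.48e-05, and adjusted p = 0.0506 with an estimated correlation). Among them DUSP6, an ERK phosphatase, rose by 0.88 (adjusted p = 0.0471), a call that ended in 15 of 21 alternatives, each control or perifosine array left out among them (adjusted p up to 0.227), while EGR1 was at 0.68 (adjusted p = 0.183) and CXCL8 at 0.80 (adjusted p = 0.175). Of them 4 rose adjusted over the list alone. Mitosis genes were lower (median -0.24 over 29, adjusted p = 1.67e-05, and adjusted p = 0.186 with an estimated correlation), with 0 members past the threshold either way. Mitosis genes also differed between arrays within groups, at a median of 0.58 above the group mates in sorafenib B. In the control and perifosine arrays this median ran from -0.20 in perifosine C to 0.20 in control C, which stood apart. Targets of ATF4, the transcription factor of the amino acid response, were higher (median 0.12 over 31, adjusted p = 0.00106, and adjusted p = 0.051 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signalling, rose by 0.96 (SE 0.15, adjusted p = 0.0208) and was the 1 member to pass over all genes, against 6 that rose and 1 that fell adjusted over the list alone. The DDIT4 call ended in 7 of 21 alternatives, among them control B, control C or any perifosine array left out (adjusted p up to 0.137). TRIB3, a pseudokinase gene of the same list, was at 0.39 (SE 0.13, adjusted p = 0.429). NF-kB targets (median 0.12, adjusted p = 0.00085), ER chaperones (0.19, adjusted p = 0.0178), FOXO targets (0.03, adjusted p = 0.0377) and p53 targets (0.06, adjusted p = 0.0377) were higher. With an estimated correlation their adjusted p values were 0.0686, 0.111, 0.078 and 0.078. Of their members 6, 0, 5 and 1 rose adjusted over the list alone. The call ended for ER chaperones without control B (adjusted p up to 0.0965). It ended for FOXO targets without control A, control B or perifosine A (up to 0.104), and for p53 targets without control A, control B, perifosine B, perifosine C or sorafenib A (up to 0.127).

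**Figure D1:**
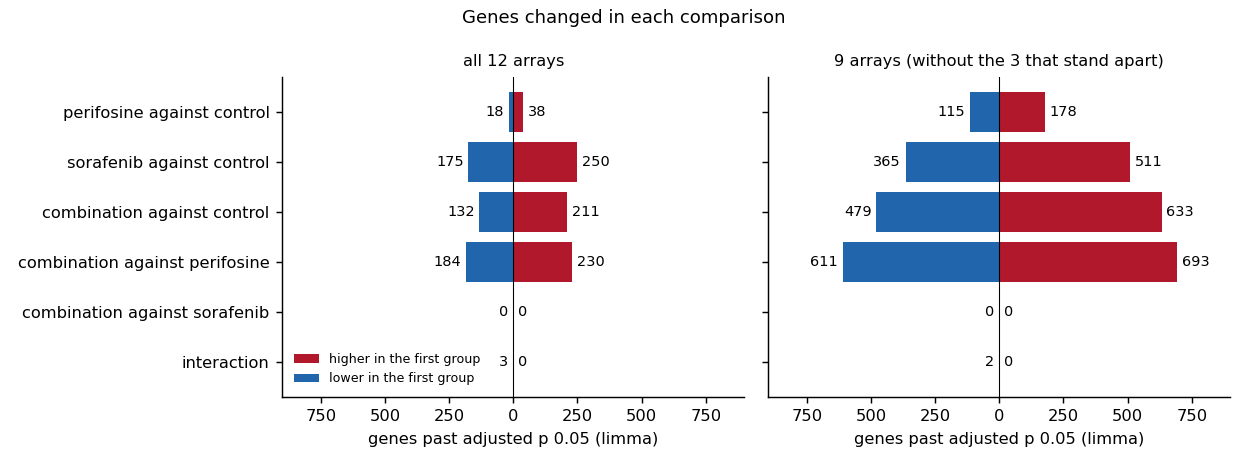
Number of genes past an adjusted p of 0.05 (limma) in each comparison, with bars to the right for genes higher and to the left for genes lower in the first group named, in all 12 arrays and in the 9 left without the 3 that stood apart. For the interaction, left means a perifosine effect that was lower with sorafenib than without it. Sorafenib against control gave 250 and 175 genes in all 12 arrays, and combination against sorafenib gave 0 in both sets.

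The comparison of sorafenib with control asked what sorafenib alone changed. ESM1, which encodes the secreted proteoglycan endocan, showed the largest change, from 17077 ± 3331 to 1481 ± 215, a log2 change of -3.52 (SE 0.18, adjusted p = 6.52e-06 by limma). SPHK1, a sphingosine kinase gene (-1.65), KRTAP4-7 (-1.59), CCL3L3 (-1.55) and LPXN, which encodes the adaptor leupaxin (-1.53), fell as well, followed by FOXQ1 (-1.48). The largest rises were in OLFML2A, from 1452 ± 361 to 7512 ± 234 (log2 change 2.40, SE 0.17, adjusted p = 5.63e-05), and in DDIT4, from 2522 ± 467 to 12178 ± 1938 (2.28, SE 0.15, adjusted p = 3.06e-05). MATN2, a matrix protein gene, rose by 2.00, the efflux transporter gene ABCC3 by 1.89, and ASNS, the asparagine synthetase gene, by 1.78. In all, 425 genes changed, 250 upward and 175 downward, of which 49 rose and 35 fell by at least 2-fold. The count without the 3 arrays that stood apart was 876, of which 355 were among the 425. Without control A, B or C it was 177, 111 or 162, and a fit of the control and sorafenib arrays alone gave 10. Of 51 called genes followed through each single array left out, 25 passed every time. Those that did not include SPHK1 and CCL3L3 above, and among genes named below TRIB3, ATF5, AARS1, SARS1, ETV4, CXCL8, PTGS2 and the 4 stromal markers.

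Targets of ATF4 were higher as a list with sorafenib. Their median log2 change was 0.56 over 31 measured genes (adjusted p = 9.09e-16 by camera, 0.00245 with an estimated correlation). Over all genes 10 of them rose and 1 fell, against 18 and 1 adjusted over the list alone. Beside DDIT4 and ASNS, the risers included PCK2 (1.71), a mitochondrial enzyme of gluconeogenesis, the glycine transporter gene SLC6A9 (1.51), and PSAT1 (1.42) and PHGDH (0.98), both enzymes of serine synthesis. TRIB3 went from 2852 ± 292 to 4757 ± 442, a log2 change of 0.74 (SE 0.13, adjusted p = 0.0152). The member that fell was ATF5 (-0.88, adjusted p = 0.0126), itself a transcription factor. Cytosolic aminoacyl-tRNA synthetase genes had a median of 0.50 over 18 genes (adjusted p = 8.76e-05, and adjusted p = 0.319 with an estimated correlation). Of these, 3 rose over all genes: AARS1 (0.98), MARS1 (0.79) and SARS1 (0.70). When adjusted over the list alone, 8 rose and 1 fell.

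Output genes of the ERK pathway were lower with sorafenib. Their median was -0.32 over 24 genes (adjusted p = 2e-07, 0.0217 with an estimated correlation), 7 fell over all genes and 10 did adjusted over the list alone. EGR1, an immediate early transcription factor gene, fell from 5344 ± 754 to 1949 ± 377 (log2 change -1.46, SE 0.17, adjusted p = 0.00183). DUSP5, an ERK phosphatase gene, changed by -1.24, ETV4 by -0.94 and CXCL8, the interleukin-8 gene, by -0.92. DUSP6 was at -0.64 (adjusted p = 0.0639).

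DNA replication genes were lower as well (median -0.31 over 30, adjusted p = 4.75e-10, 0.0217 with an estimated correlation). Over all genes 6 of them fell, among them FEN1, the flap endonuclease gene (-1.11), CCNE1, which encodes cyclin E1 (-1.01), and CDT1 (-0.78). In all 12 fell adjusted over the list alone. Ribosome biogenesis genes had a median of -0.40 over 28 (adjusted p = 3.23e-09, 0.00946 with an estimated correlation). The 3 that fell over all genes were LYAR (-0.81), NOP2 (-0.67) and BYSL (-0.66), against 8 adjusted over the list alone. The LYAR call ended in 15 of 21 alternatives (adjusted p up to 0.285) and those of NOP2 and BYSL in 6 each (up to 0.166 and 0.186). Single arrays that ended the LYAR call were all but sorafenib B and C, for NOP2 control B, control C and sorafenib C, and for BYSL each control array. The BCL2 family was lower as a list (median -0.34 over 17, adjusted p = 0.000389, 0.0217 with an estimated correlation). In it 0 members passed over all genes and 3 fell adjusted over the list alone, among them PMAIP1 (-0.86) and BCL2L1 (-0.58), which encode a pro-apoptotic and an anti-apoptotic protein.

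The list of fibroblast and stromal markers, written as markers of another cell type, was higher with sorafenib (median 0.52 over 10 genes, adjusted p = 2.81e-06, 0.0217 with an estimated correlation). The collagen I genes COL1A1 and COL1A2 rose by 1.23 and 1.12, DCN, the decorin gene, by 0.89 and THY1 by 0.87. These were the 4 that passed over all genes, against 5 adjusted over the list alone. COL1A2 was already at 24340 ± 5237 in the control arrays and reached 52761 ± 10410. COL3A1 (0.28, adjusted p = 0.541) and LUM (-0.01, adjusted p = 0.984) stayed near the background, at 271 ± 26.4 and 272 ± 17.2 in controls.

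A further 4 lists called with sorafenib lost the call with an estimated correlation. Hypoxia and glycolysis genes were lower (median -0.16 over 28, adjusted p = 0.0037, and adjusted p = 0.175 with an estimated correlation), with falls in BNIP3 (-0.81) and the glucose transporter gene SLC2A1 (-0.73) over all genes. These calls ended in 14 and 13 of 21 alternatives, each control or sorafenib array left out among them (adjusted p up to 0.141 and 0.144). Adjusted over the list alone 7 fell and 1 rose. Heat shock genes were lower (median -0.10, adjusted p = 0.0154, and adjusted p = 0.194 with an estimated correlation). Fatty acid synthesis genes (0.32, adjusted p = 0.011) and cholesterol genes (0.25, adjusted p = 0.0394) were higher, with adjusted p values of 0.319 and 0.326 with an estimated correlation. In these 3 lists 0 members passed over all genes, and adjusted over the list alone 2 heat shock genes fell. These 3 calls also ended without single arrays: heat shock without control C or sorafenib C, fatty acid synthesis without control A or sorafenib B, and cholesterol without control A, control B, sorafenib A or sorafenib C. Their adjusted p then reached 0.0821, 0.119 and 0.246. In all 12 arrays 11 lists were called with sorafenib, and 13 in the 9 arrays left without those that stood apart. The 2 added there were NF-kB targets (median -0.18, adjusted p = 0.00986, against -0.03 and adjusted p = 0.0677 in all 12) and autophagy and lysosome genes (0.09, adjusted p = 0.0229, against 0.14 and adjusted p = 0.0961). Over all genes in all 12 arrays, 2 NF-kB targets fell, among them PTGS2, the cyclooxygenase-2 gene (-1.31). No autophagy gene did so or rose, and 5 rose adjusted over the list alone. The p53 targets were not called (median 0.09, mean -0.02, adjusted p = 0.966), and CDKN1A, which encodes the cell cycle inhibitor p21, fell by 1.24.

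**Figure D2:**
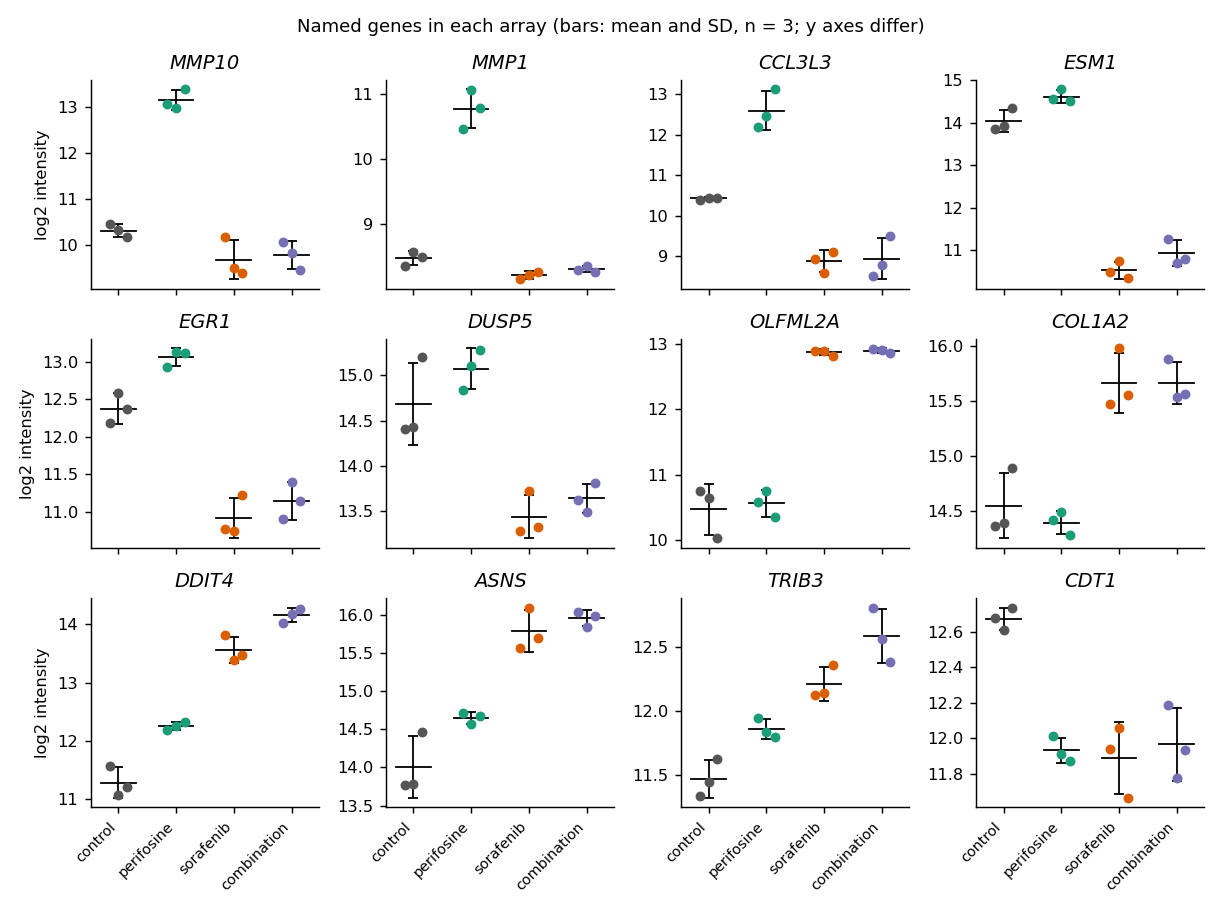
Log2 intensity of 12 named genes in each array (points, n = 3 per group) with the group mean and SD (lines and bars), and a separate y axis for each gene. MMP10, MMP1 and CCL3L3 are high in the perifosine arrays alone, ESM1, EGR1 and DUSP5 are low and OLFML2A and COL1A2 high in both groups with sorafenib, and CDT1 is low in all 3 treated groups. The group means of DDIT4 go from 2522 in controls to 18354 in the combination.

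The comparison of the combination with control asked what both drugs together changed. The genes named first were mostly those of sorafenib alone. DDIT4 rose by a log2 value of 2.88 (SE 0.15, adjusted p = 6.8e-06 by limma), to an intensity of 18354 ± 1592. OLFML2A rose by 2.43, ASNS by 1.95, ABCC3 by 1.92 and PCK2 by 1.92. ESM1 fell by 3.12, to 1977 ± 433, and falls followed in SPHK1 (-1.67), KRTAP4-7 (-1.57), CCL3L3 (-1.49) and CYP1B1, a cytochrome gene (-1.41). TRIB3 rose to 6195 ± 920, a log2 change of 1.11 (SE 0.13, adjusted p = 0.0015). In all, 343 genes changed, 211 upward and 132 downward, and 56 rose and 26 fell by at least 2-fold. Without the 3 arrays that stood apart the count was 1112, of which 321 were among the 343. It was 147, 89 or 163 without control A, B or C, 160, 146 or 119 without combination A, B or C, and 1046 without sorafenib B. Of 51 called genes followed through each single array left out, 25 passed every time, DDIT4, OLFML2A, ASNS, ABCC3, PCK2, ESM1, KRTAP4-7, CYP1B1 and TRIB3 among them. SPHK1 and CCL3L3 did not, nor, of genes named below, DUSP5, ETV4, BYSL, NOP2, RRP12, WARS1, MX1, IRF9, IRF7, TSC22D3, SLC2A1, ADM and the 4 stromal markers.

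Of the 12 lists called in the combination, 5 also were with an estimated correlation. ATF4 targets had a median of 0.72 (adjusted p = 7.06e-25 by camera, 0.000465 with an estimated correlation), with 10 of 31 genes higher over all genes, and 21 higher and 1 lower adjusted over the list alone. DNA replication genes (median -0.33, adjusted p = 3.87e-11, 0.0309 with an estimated correlation) included 6 that fell, among them FEN1 (-1.04), CCNE1 (-1.03) and MCM10 (-0.89). Ribosome biogenesis genes were at -0.37 (adjusted p = 4.07e-11, 0.00497 with an estimated correlation), with falls in BYSL (-0.74), NOP2 (-0.72) and RRP12 (-0.62). ERK output genes were at -0.35 (adjusted p = 6.57e-06, 0.0499 with an estimated correlation), where EGR1 (-1.23), DUSP5 (-1.04) and ETV4 (-0.84) fell. Stromal markers were at 0.52 (adjusted p = 1.22e-05, 0.0393 with an estimated correlation), and COL1A2 (1.12), DCN (0.89), THY1 (0.85) and FBLN1 (0.61) rose. Adjusted over the list alone, 10 replication genes, 5 ribosome biogenesis genes and 6 ERK output genes fell, and 5 stromal markers rose.

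The other 7 lists lost the call with an estimated correlation. In the 9 arrays left without those that stood apart 13 lists were called, the 12 and cholesterol genes (median 0.24, adjusted p = 0.0122, against 0.11 and adjusted p = 0.608 in all 12). Aminoacyl-tRNA synthetase genes were higher (median 0.55, adjusted p = 1.63e-05, and adjusted p = 0.26 with an estimated correlation), where AARS1 (1.03), SARS1 (0.96), MARS1 (0.94) and WARS1 (0.85) rose. Interferon genes were higher (0.16, adjusted p = 0.0067, and adjusted p = 0.094 with an estimated correlation), with rises in MX1 (1.22), IRF9 (0.81) and IRF7 (0.55). FOXO targets (0.16, adjusted p = 0.0145) and autophagy genes (0.11, adjusted p = 0.0124) were also higher. BCL2 family (-0.18, adjusted p = 0.00866), heat shock (-0.15, adjusted p = 0.0143) and hypoxia genes (-0.14, adjusted p = 0.00584) were lower. With an estimated correlation these had adjusted p values of 0.058 (FOXO, autophagy and BCL2 lists), 0.156 and 0.136. Adjusted over the list alone, 5 synthetase, 3 interferon, 4 FOXO and 3 autophagy genes rose. On that scale 1 BCL2 family gene and 7 hypoxia genes fell and 1 hypoxia gene rose. Over all genes 2 FOXO targets rose, FBXO32 (1.29) and TSC22D3 (1.07), and 2 hypoxia genes fell, SLC2A1 (-0.81) and ADM (-0.83). The heat shock call ended without control C or combination B (adjusted p up to 0.0854).

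The comparison of the combination with perifosine asked what sorafenib added to perifosine. It held several of the genes that perifosine alone had raised: falls were seen in MMP10 (-3.37), CCL3L3 (-3.66), CCL3 (-3.23), NPPC (-2.63) and MMP1 (-2.47), next to ESM1 (-3.69, SE 0.18, adjusted p = 3.81e-06 by limma). PTGS2 fell by 2.56. The largest rises were in MATN2 (2.52), OLFML2A (2.34), DDIT4 (1.91), CPA4 (1.91) and KRT80, a keratin gene (1.72), and TRIB3 rose by 0.73 (SE 0.13, adjusted p = 0.0115). In all, 414 genes changed, 230 upward and 184 downward, and 65 rose and 75 fell by at least 2-fold. The count was 1304 without the 3 arrays that stood apart, of which 408 were among the 414. It was 237 or 235 without combination A or C, 240, 222 or 215 without perifosine A, B or C, and 1050 without sorafenib B. Of 50 called genes followed through each single array left out, 34 passed every time. TRIB3 did not, nor, of genes named below, PMAIP1, BAK1 and VEGFA.

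Against perifosine, 11 lists were called in the combination and 4 of these also with an estimated correlation. ERK output genes were lower (median -0.49, adjusted p = 6.98e-12 by camera, 0.0138 with an estimated correlation), and 7 of 24 fell over all genes, among them EGR1 (-1.91), CXCL8 (-1.50), DUSP5 (-1.43) and DUSP6 (-1.28). ATF4 targets were higher (0.48, adjusted p = 1.38e-17, 0.00166 with an estimated correlation), with 11 that rose. Stromal markers were higher (0.52, adjusted p = 9.97e-07, 0.0276 with an estimated correlation), and DCN (1.53), COL1A2 (1.27) and THY1 (1.14) rose. The BCL2 family was lower (-0.21, adjusted p = 0.00153, 0.0439 with an estimated correlation), with falls in PMAIP1 (-1.34) and BAK1 (-0.80), both pro-apoptotic. Adjusted over the list alone, 10 ERK output and 2 BCL2 family genes fell, 17 ATF4 targets rose and 1 fell, and 5 stromal markers rose.

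In the same comparison, mitosis genes (median 0.28, adjusted p = 5.48e-05) and aminoacyl-tRNA synthetase genes (0.54, adjusted p = 8.05e-06) were higher, each with an adjusted p of 0.233 with an estimated correlation. NF-kB targets (-0.10, adjusted p = 0.00153), ribosome biogenesis (-0.19, adjusted p = 0.000859), cholesterol (-0.22, adjusted p = 0.00114), ER chaperone (-0.14, adjusted p = 0.0106) and hypoxia genes (-0.08, adjusted p = 0.0109) were lower. With an estimated correlation their adjusted p values were 0.132, 0.0709, 0.173, 0.146 and 0.196. Over all genes 3 synthetase genes rose, while 3 NF-kB, 2 ribosome biogenesis, 1 ER chaperone and 0 hypoxia genes fell. Adjusted over the list alone, 4 synthetase genes rose, 4 NF-kB, 2 ribosome biogenesis, 1 ER chaperone and 6 hypoxia genes fell, and 1 hypoxia gene rose. That gene, VEGFA, rose by 1.16 (adjusted p = 0.0432) and was the 1 hypoxia gene to pass over all genes, against the direction of its list. The ER chaperone call ended without combination B (adjusted p = 0.0911). In the 9 arrays left without those that stood apart 13 lists were called. The 2 added were heat shock genes (median -0.12, adjusted p = 0.0487, against -0.11 and adjusted p = 0.108 in all 12) and Hodgkin cell markers (-0.07, adjusted p = 0.0355, against -0.06 and adjusted p = 0.0893).

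The comparison of the combination with sorafenib asked what perifosine added to sorafenib, and 0 genes passed. The lowest adjusted p was 0.597 by limma, and 643 genes (3.41%) had an unadjusted p under 0.05. That share is no larger than a threshold of 0.05 gives on average where nothing changes. The count was 0 too in every alternative fit run and without the 3 arrays that stood apart, where 1051 genes had an unadjusted p under 0.05. The 95% confidence interval reached a median of 0.32 log2 to either side, and for 96.5% of genes the interval lay within a 2-fold change. Many of these genes lie near the background, where changes are understated, and among the 9587 genes with a mean log2 intensity of at least 9 the median was 0.40. All these intervals use a spread shared by the 4 groups. Deviations from group mates had an SD of 0.55 in sorafenib B and 0.34 in combination A, against 0.19 to 0.20 in the perifosine arrays. The intervals may therefore be too narrow for the 2 groups compared here. MMP10, which perifosine alone had raised by 2.83, differed by 0.10 (95% interval -0.37 to 0.56). MMP1 differed by 0.10 (0.24 with normexp), but at a mean of 296 with sorafenib and 316 with both it lies near the background, so its interval does not bound the change in transcript. The intervals are not adjusted for the number of genes, and not all held 0. DDIT4 was at 0.60 (0.28 to 0.92) and TRIB3 at 0.37 (0.10 to 0.65), each with an adjusted p of 0.999. The largest differences were in CLN8 (1.25, SE 0.51, adjusted p = 0.999) and THBS1, the thrombospondin-1 gene (-1.26, SE 0.20, adjusted p = 0.597), which were named after their values were seen.

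Of the gene lists, 3 were called in the combination against sorafenib, and 0 of them with an estimated correlation. ATF4 targets were at a median of 0.17 (adjusted p = 0.000155, and adjusted p = 0.125 with an estimated correlation) and interferon genes at 0.14 (adjusted p = 0.000703, and adjusted p = 0.125). Fatty acid synthesis genes were at -0.15 (adjusted p = 0.00138, and adjusted p = 0.336), a call that ended without sorafenib B or without combination B, with adjusted p values of up to 0.11. No member of the 3 lists passed, also when adjusted over the list alone. By camera at its preset correlation 7 lists were called without the 3 arrays that stood apart, these 3 and 4 more. The 4 were synthetase genes (median 0.08, adjusted p = 0.0385, against 0.02 and adjusted p = 0.64 in all 12), cholesterol genes (-0.11, adjusted p = 0.0133, against -0.22 and adjusted p = 0.0705), ERK output genes (0.12, adjusted p = 0.0166, against 0.14 and adjusted p = 0.0705) and metallothioneins (-0.28, adjusted p = 0.0133, against -0.29 and adjusted p = 0.489).

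The interaction asked whether perifosine's effect differed with and without sorafenib. It passed for 3 genes, all with a lower effect in the presence of sorafenib: MMP10 (-2.73, SE 0.30, adjusted p = 0.0127 by limma), MMP1 (-2.21, SE 0.19, adjusted p = 0.00218) and FERMT1, the kindlin-1 gene (-1.20, SE 0.15, adjusted p = 0.0281). The MMP1 value is understated, since that gene lies near the background in the 3 groups other than perifosine (-2.97 with normexp). FERMT1 went from 3348 ± 338 to 7526 ± 630 with perifosine alone, and was at 3305 ± 223 with sorafenib and 3234 ± 28.5 with both. The count was 1 without control C, perifosine A, perifosine C or combination B. MMP1 passed without any single array, with an adjusted p of up to 0.0181. MMP10 did not pass without those 4 arrays (adjusted p up to 0.0707). FERMT1 passed without control B (adjusted p = 0.0343) or sorafenib B (0.0387) and not without any other single array (up to 0.134). Without the 3 arrays that stood apart the count was 2, both among the 3. An unadjusted p under 0.05 was reached by 921 genes (4.89%), about the share that this threshold gives on average where nothing changes. DNA replication genes were at a median of 0.42 (adjusted p = 1.68e-13 by camera, 0.0487 with an estimated correlation), since their median change with perifosine was -0.44 without sorafenib and 0.00 with it. Against control these genes were also lower with sorafenib alone (-0.31) and with both drugs (-0.33), so they were low in all 3 treated groups. Over all genes 0 of them passed and 4 did adjusted over the list alone. Cholesterol genes were at -0.51 (adjusted p = 4.42e-07, and adjusted p = 0.117 with an estimated correlation). Ribosome biogenesis (0.19, adjusted p = 0.0193) and mitosis genes (0.16, adjusted p = 0.00325) had adjusted p values of 0.314 and 0.528 with an estimated correlation. Of these 3 lists 0 members passed over all genes, and 1 mitosis gene did adjusted over the list alone. The mitosis call ended without perifosine C or sorafenib C (adjusted p up to 0.0956), and that of ribosome biogenesis without control A, sorafenib B or combination C (up to 0.156). By camera at its preset correlation 8 lists were called in the 9 arrays left without those that stood apart, these 4 and 4 more. The 4 were ER chaperones (median -0.20, adjusted p = 0.000215, against -0.16 and adjusted p = 0.0519 in all 12), fatty acid synthesis (-0.25, adjusted p = 0.00218, against -0.26 and adjusted p = 0.0519), ERK output (-0.20, adjusted p = 0.00274, against -0.11 and adjusted p = 0.0598) and autophagy genes (-0.20, adjusted p = 0.0101, against -0.14 and adjusted p = 0.135).

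**Figure D3:**
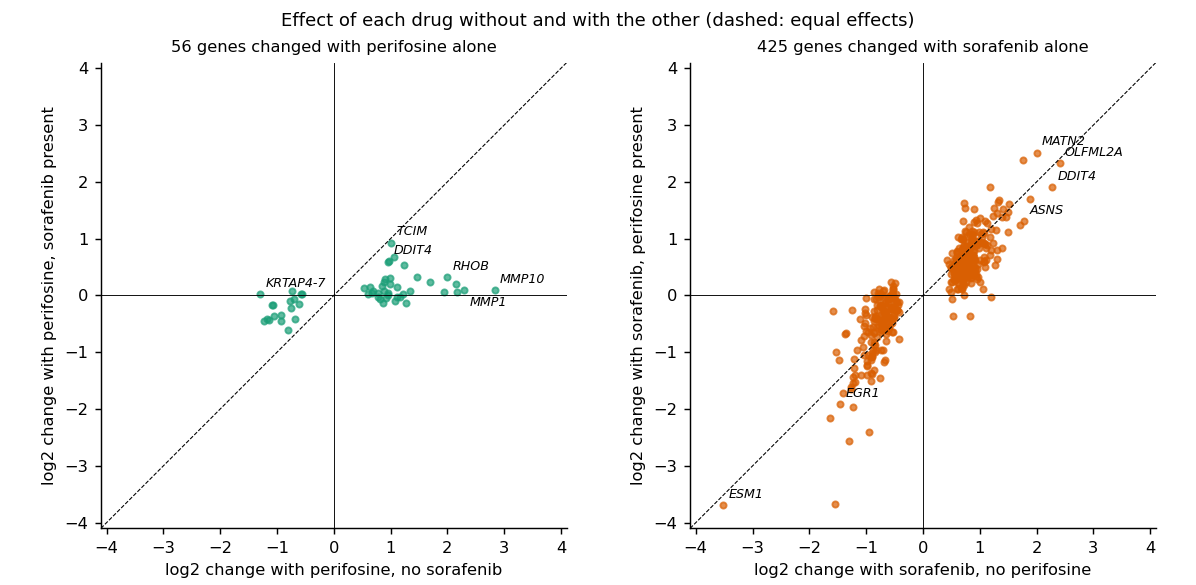
Log2 change of genes past an adjusted p of 0.05 in the single-drug comparison, without the other drug (x axis) and in its presence (y axis), for 56 genes of perifosine and 425 of sorafenib; a point is a gene and the dashed line marks equal effects. All 56 perifosine genes had a smaller change with sorafenib present, and for 14 the 95% interval there excluded 0. Choosing genes by their change on the x axis by itself favours a smaller value on the y axis, for both drugs. They kept 17.1% of their summed change, and the sorafenib genes kept 79.0%.

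The effect of each drug was also set against its effect in the presence of the other, in arrays that the 2 estimates do not share. For the 56 genes of perifosine, 44 had the same sign with sorafenib present and the summed change kept 17.1% of its size, 13.9% for the 38 that rose and 26% for the 18 that fell. For the 425 genes of sorafenib, 404 had the same sign with perifosine present and 79.0% was kept, 82.9% for the 250 that rose and 73.4% for the 175 that fell. Across all genes, which are not independent replicates, the effects correlated with r = 0.10 for perifosine and r = 0.59 for sorafenib. Calls of the comparisons with control overlapped: 150 genes rose and 93 fell both with sorafenib and with the combination, against 2.80 and 1.23 for independent lists, with 0 called in opposite directions. Perifosine and sorafenib shared 4 rises and 5 falls, against 0.504 and 0.167 for independent lists, and 10 genes were called in opposite directions. Perifosine and the combination shared 5 rises and 8 falls (0.425 and 0.126 for independent lists), with 3 opposite. These comparisons use the same control arrays, and in 50 simulations of unchanged groups against those controls the highest overlap was 0. In data simulated with nothing changed 0 genes were called on average, so that value does not measure what sharing the controls adds to lists of called genes. The controls were too few to split, so part of the overlap may come from sharing them.

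**Figure D4:**
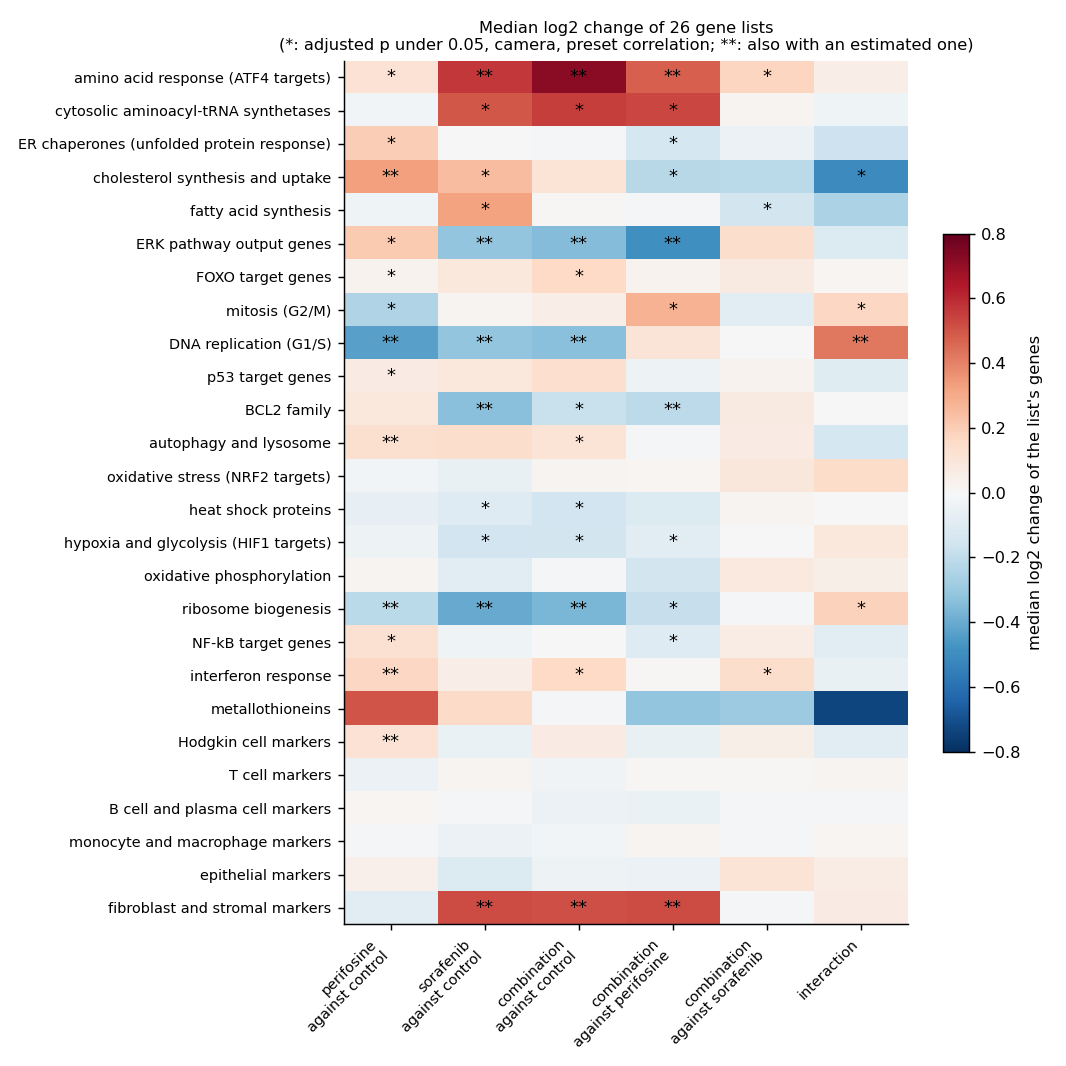
Median log2 change (colour) of the genes of 26 lists in the 6 comparisons, with a star where camera gave an adjusted p under 0.05 with its preset correlation and a second star where it also did with an estimated one. ATF4 targets and stromal markers are higher and ERK output genes lower in the 3 comparisons where sorafenib was added, with medians from 0.48 to 0.72, 0.52 and -0.49 to -0.32.

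The lists of other cell types were not called in any comparison, in all 12 arrays or in the 9, except for the stromal markers above. Their lowest adjusted p over the 6 comparisons was 0.663 for T cell, 0.626 for B cell and plasma cell, 0.847 for monocyte and macrophage and 0.23 for epithelial markers. Targets of NRF2 in oxidative stress (17 genes) and oxidative phosphorylation genes (28) had a lowest adjusted p of 0.0705, both in the combination against sorafenib. For the 8 metallothionein genes measured it was 0.156 in all 12 arrays, for an interaction with a median of -0.74. This median was -0.18 without the 3 arrays that stood apart (adjusted p = 0.248), and the list was called in the combination against sorafenib, as given above. Oxidative phosphorylation and metallothionein genes were lower in the 3 arrays that stood apart, as given above for each.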

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

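Chosen only after the result was seen were the tests of a mislabelled sample, of an unequal response and of short transcripts, the tests without the 3 arrays that stood apart, and the test of genes that sorafenib lowers.

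The effect of perifosine differed with and without sorafenib for 3 genes by the interaction test: MMP10 (-2.73), MMP1 (-2.21) and FERMT1 (-1.20). It also differed for 4 gene lists by camera, with median interactions of -0.51 for cholesterol synthesis and uptake, 0.16 for mitosis, 0.42 for DNA replication and 0.19 for ribosome biogenesis. With an estimated correlation 1 of these 4, DNA replication, was called. Against control this list was also lower with sorafenib alone (-0.31) and with both drugs (-0.33). Without the 3 arrays that stood apart 8 lists were called by camera, with ER chaperones (-0.20), fatty acid synthesis (-0.25), ERK output (-0.20) and autophagy genes (-0.20) added. MMP1 lies near the background in the groups other than perifosine, so its value is understated.

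The first pattern is that changes with perifosine were small in the presence of sorafenib, where the 56 genes kept 17.1% of their change (13.9% for the 38 that rose, 26% for the 18 that fell). Selection of genes with chance high values would lower any second measurement. With 1 perifosine and 1 control array held out, the 56 genes of lowest p in the other 10 arrays were taken anew. The held-out pair kept 82.1% of their change on average over 9 choices (69.1% to 93.6%). This argues against selection on chance values of single arrays as the whole cause. The held-out arrays come from the same 2 groups, so a chance difference common to all arrays of a group was not tested. Without the 3 arrays that stood apart the same 56 genes kept 16.7%, and the 293 genes called there kept 18.6%, which argues against those arrays. The 13 risers that sorafenib alone did not lower kept 17.4% of their rise (95% interval 6.80 to 29.4 over 10000 resamples of genes, which are not independent). The same sorafenib arrays chose these 13 genes and enter the change measured, which by itself lowers the share kept. The value therefore does not decide whether lowering to the background is the whole cause. A block of perifosine's effect by sorafenib may remain as a hypothesis, found and tested on the same data, and 3 of the 56 genes passed the adjusted interaction test. Of the 18 falls, 5 were also called with sorafenib alone. KRTAP4-7, lower by 1.29 with perifosine, was at -1.59 with sorafenib and -1.57 with both. For such genes a small further change need not be a block. Of the 38 rises 4 were shared, and 10 genes were called in opposite directions.

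The second pattern is that control C, sorafenib B and combination A stood apart from their group mates. On the 876 genes that part arrays with and without sorafenib, 0 of the 3 lay nearer to the other state, which argues against a label from the other sorafenib state; a swap within a state was not tested. The deviations of control C and sorafenib B, which share no drug, correlated across genes with r = 0.597 (genes are not independent replicates), which argues against an unequal drug response as the common cause. Ribosomal protein genes, whose mRNAs are short, had a median deviation of -0.257 or lower in all 3 arrays, so a lower yield of short transcripts could be a cause. No biological explanation was tested, and a difference in the cultures stays open.

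The third pattern is the rise of fibroblast and stromal markers with sorafenib. It was present without the 3 arrays that stood apart (adjusted p = 2.05e-05), which argues against those arrays. RNA from fibroblasts may be a source, and 2 criteria were used for it, the second in place of the first before its value was seen. By the first, at least 2 of 5 markers (COL1A1, COL1A2, COL3A1, DCN and LUM) needed a 95% upper bound under 0.62, which is COL1A1's log2 change divided by 2. It was met by 1 of 5 markers, LUM (0.24), while COL3A1 had a bound of 0.69, so the first criterion did not exclude fibroblast RNA. COL1A1 could not meet it, since the limit is taken from its own change. The prediction for fibroblast RNA also had all 5 markers rise, and LUM was at -0.01, so that prediction was not met either. By the second, COL3A1 gained 0.234% of the intensity that COL1A2 gained, a share under the limit written beforehand for excluding fibroblast RNA. That share compares different probes, 1 of them near the background, and assumes a fibroblast profile, so nothing is read from it. Fibroblast RNA and expression by the line itself cannot be told apart here, since LUM and COL3A1 lie near the background. PDGFRB and POSTN, also on the list, lie near it too, at 337 and 346 in controls and 336 and 470 with sorafenib. An effect of sorafenib on the line stays open.

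Other splits of the 6 arrays were counted for each pairwise comparison. With 10 splits the share cannot be under 0.05. For perifosine the real split gave 56 genes and the highest other 0, and for sorafenib 425 and 0. For the combination it gave 343 and 0 against control, and 414 and 0 against perifosine. In these 4 comparisons 1 of 10 splits, the real one, gave as many genes. The other splits mix arrays of the 2 groups compared, which widens the spread of genes that differ between them. Their counts of 0 therefore do not measure what chance gives. For the combination against sorafenib the real split and the highest other gave 0, so all 10 of 10 did. For the interaction 3 of 100 draws that dealt the 12 arrays into 4 groups, the real one included, gave at least 3 genes, with 3 as the highest other. These draws mix the treatments within groups. The median SE over all genes was 0.21 in the real groups and 0.22 at the median of the draws, while that of MMP1, which is high in the perifosine arrays alone, went from 0.19 to 1.04. Genes that respond to a drug are thus less easily called in the draws, which leaves open whether chance gives 3 genes.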

How the results depend on the processing

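Array quality weights, normexp, the limit on mean log2 intensity and leaving out the 3 arrays that stood apart were chosen after the data were seen. Over all alternatives 4158 values of single genes had the same direction and side of the threshold, 652 lost the call, 59 gained it and 0 reversed. Of the gene list values 3221 were the same, 81 lost the call, 84 gained it and 2 reversed. With fry 15 list calls were lost and 3 gained. The lost calls include ATF4 targets, interferon and fatty acid synthesis genes in the combination against sorafenib (adjusted p = 0.127, 0.127 and 0.366 by fry). In the interaction cholesterol, mitosis and ribosome biogenesis genes lost it (0.226, 0.526 and 0.233), while DNA replication genes kept it (0.0398).

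Without the 3 arrays the counts of genes were 293 for perifosine, 876 for sorafenib, 1112 for the combination against control and 1304 against perifosine. With array quality weights they were 349, 1249, 1181 and 1306, and 15 for the interaction. With normexp they were 22, 143, 127 and 263, and 1 for the interaction. With trend and robust they were 34 for perifosine and 254 for sorafenib. With the letter as a replicate block perifosine gave 37. In fits of only the 2 groups compared, which have fewer arrays, the counts were 126 for perifosine, 10 for sorafenib and 843 for the combination against perifosine. With genes of mean log2 of at least 9 the interaction gave 1. Fewer arrays do not account for the higher counts of perifosine and of the combination against perifosine in fits of 2 groups. Those fits leave out sorafenib B, and without that array alone these counts were 155 and 1050. That array enters these 2 comparisons only through the shared spread. For the other counts, apart from the fewer arrays or genes, the cause was not tested. The combination against sorafenib gave 0 in every alternative run.

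Leaving out each array in turn gave 11 to 155 genes for perifosine, 111 to 570 for sorafenib, 89 to 1046 and 215 to 1050 for the combination against control and perifosine, and 1 to 4 for the interaction. At 2-fold as well, sorafenib and the combination shared 32 rises and 20 falls, perifosine and sorafenib 0 and 1, and perifosine and the combination 0 and 2, since fewer genes pass.

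The 2 lists that reversed did so without sorafenib B, in the combination against sorafenib. Mitosis genes went from a median of -0.088 to 0.090 (adjusted p = 0.0450), with a range of -0.21 to 0.090 when each array was left out. Oxidative phosphorylation genes went from 0.077 to -0.17 (adjusted p = 0.0140, range -0.17 to 0.28). That array deviated by 0.58 and -1.0 in these lists.

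The letters were not seen to pair the arrays: 5 of 18 same-letter pairs had a correlation of deviations over 0.1 (-0.57 to 0.49), and their median was -0.02 against 0.02 for other letters. Background correction from detection p values, with quantile normalization or a median shift, the detection filters and the beadchip as a block were not run, as they need the columns not used here. Log2 without background correction, series matrix values and no filter are the choices used throughout. With 70.2% of probes under 512, signal over background limits what could be seen of dim genes.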

Other observations

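The genes below were chosen after their values were seen. Of perifosine's 56 genes, all 56 had a smaller change in the presence of sorafenib, and for 14 the 95% interval there excluded 0 with the same sign. The genes were chosen by their change without sorafenib, which by itself favours a smaller second value, so the count of 56 is not evidence of its own. TCIM kept most of its change, at 1.0 without sorafenib and 0.93 with it (adjusted p = 0.597). TBC1D2 was at -0.81 and -0.61, THBD at 1.05 and 0.67, DDIT4 at 0.96 and 0.60, and HEY1 at 0.95 and 0.58. With sorafenib present these 4 had an adjusted p of 0.999. Their calls with perifosine alone also rest on few arrays: of 12 single arrays left out, the call ended without 10 for TCIM (adjusted p up to 0.224), 7 for TBC1D2, 5 for THBD, 5 for DDIT4 and 7 for HEY1. Each perifosine array was among these for all 5 genes.

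THBS1 was low in both groups with perifosine. Its intensity was 4821 ± 595 in controls, 2488 ± 212 with perifosine, 4875 ± 1553 with sorafenib and 1995 ± 305 with both. The log2 change was -0.95 for perifosine (adjusted p = 0.0932) and -1.26 for perifosine added to sorafenib (adjusted p = 0.597), neither of which passed. For the combination against control it was -1.28 (adjusted p = 0.00939), a call that ended without control B (adjusted p = 0.0546).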
